A study of Mus musculus with 3 samples.

How the data were processed

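RNA of RAW264.7 cells, a mouse macrophage line, was measured by paired-end RNA sequencing in 3 libraries, with 1 library each for untreated control cells, cells given 0.5 mM hydroxyurea (HU), and cells given HU and gold nanocages at the same time. Per the labels' protocols, cells grew in medium with 10% serum, RNA was taken after 12 hours, and the libraries were made from 1 µg of RNA with an integrity number above 7. A library of cells given gold nanocages without HU was not analysed here. The dose and solvent of the nanocages are not given in the sources used here.

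The authors deposited 1 table of 46078 Ensembl genes with a whole-number read count per gene and library, which is not normalized. The FPKM columns of the deposited table are, per the file headers, fragments per kilobase scaled to the library; each value equals the count divided by the exonic gene size and by the summed count of its library, within rounding, for 100% of genes in each library. The exonic gene size, per the file headers, is a length in bases and counts as an other kind of value. Per the submitters' processing notes, the tools named were bcl2fastq 2.17.1.14, cutadapt, HISAT2 2.0.1, HTSeq 0.6.1, SAMtools 0.1.18 and DESeq, with the genome build mm10. The role and settings of each tool, the annotation release and the strand setting of the counting are not given in the sources used here. Without a known strand setting, reads of genes that overlap on opposite strands cannot be told apart, and how reads shared by near-identical copies were counted is likewise not given in the sources used here.

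Gene symbols and GO terms were taken from the deposited table, in which 4 genes lack a symbol. Biotypes and coordinates came from GENCODE M21 on the same mouse assembly, which holds 98.2% of the table's gene identifiers. Each symbol was represented by its gene identifier with the most reads. The table gives no biotype, so a planned restriction to protein-coding genes by the table was replaced by the GENCODE biotype after the data were seen.

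The main measure was the log2 ratio of FPKM values with a pseudocount of 1 FPKM, which understates the ratio of low genes. Genes were counted as apart at a ratio of at least 2-fold on that scale, among genes with FPKM of at least 1 in either library of a contrast. With 1 library per group, no p-value or standard error was computed for a difference between conditions. Percentiles among random lists and binomial intervals over genes describe these libraries only. Folds of named genes are plain ratios of CPM, counts scaled by the library's summed count, with exact (Clopper-Pearson) 95% intervals from the read counts of both libraries. These intervals cover counting error only, because the reads carry no molecular identifiers and no culture was repeated. A gene is called above or below counting error where its interval excludes 1. Among 10849 genes with mean FPKM of at least 1, 18.7% were above and 20.1% below it in HU against control. These shares were 8.35% and 7.78% for HU plus gold nanocages against HU, and 19.6% and 20.1% for HU plus gold nanocages against control. Counts of list members are to be read beside these shares. The summed counts were 14990564 in control, 20057329 in HU and 18644333 in HU plus gold nanocages, so 1 read stood for 0.0667, 0.0499 and 0.0536 CPM. A gene without reads has an upper limit of 3 counts, or 0.200, 0.150 and 0.161 CPM.

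Before the data were examined, 35 gene lists, the rule for named genes and most of the alternative settings were fixed. Named genes were the 10 highest and 10 lowest log2 ratios per contrast among genes with FPKM of at least 5 in either library, without predicted genes and antigen receptor segments. Pseudogenes were to be left out only if the table gave a biotype, so they stayed in. To these were added up to 4 members of each list with the largest absolute log2 ratio, and Rrm1, Rrm2, Rrm2b, Cdkn1a, Mdm2, Map1lc3b, Sqstm1, Becn1, Bcl2 and Bax. Some genes that the rule names are not reported here. Genes named outside the rule are identified as such. For each list the median log2 ratio of members with mean FPKM of at least 1 was placed among the medians of 10000 random lists matched on 20 bins of mean expression. A list was described as standing apart below percentile 2.5 or above 97.5 with at least 5 measured members, which 30 lists had. GO terms of 15 to 200 measured members were treated in the same way, with random genes drawn with replacement and bounds of 0.5 and 99.5.

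The share of genes returning toward control was the share, among genes at least 2-fold apart between HU and control, whose value with gold nanocages lay at least 50% of the log2 distance back. The HU library enters both the choice of genes and the return, so the share was set beside 100 draws of counting noise alone. Counts of genes apart and the overlap of the contrasts that share the control were set beside 100 such draws too. All draws were made around observed counts, which already hold counting noise, so their numbers are approximate. The rules were tested on simulated counts for HU against control over 7736 genes, those with FPKM of at least 5 from the pooled reads of both libraries. Of 50 genes each simulated at 1.5, 2, 3 and 4-fold, 0%, 22%, 100% and 100% were called 2-fold apart, beside 0.0398% of 7536 unshifted genes, whose counting intervals held the true ratio in 95.3%. Of 100 simulated lists of 30 members without a shift, 7% stood apart, and 100% did with a log2 shift of 0.1. The simulated counts held counting noise only, with genes varying independently. These rates therefore need not hold for the measured genes and lists, whose members can vary together. Nor do they cover genes of lower FPKM, to which the rules were also applied and where counting noise is larger.

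Alternatives were a pseudocount of 0.1 or 5 FPKM, no filter or a filter at 5 FPKM, median-of-ratios scaling, scaling of each library's FPKM values to the same larger sum, a 1.5-fold threshold, other members or unmatched random lists, and GO terms of 10 to 500 members. Added after the data were seen were the GENCODE biotype, a random split of the HU reads, and log2 ratios less the medians of 20 gene length bins and then of 20 GC bins, with GC from the longest GENCODE transcript. The analysis used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.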

Results

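The transcriptomes of 3 cultures of RAW264.7 macrophages were compared, 1 library each for control cells, cells given 0.5 mM hydroxyurea (HU) for 12 hours, and cells given HU together with gold nanocages. HU inhibits ribonucleotide reductase and stalls DNA replication. The labels frame the nanocages as a treatment that rescues HU-damaged cells. In control, HU and HU plus gold nanocages 10801, 10907 and 10909 genes reached 1 FPKM. No difference below has a replicate check, since each condition is 1 library. Macrophage genes were abundant, with Lyz2, chosen after its values were seen, at 1452, 1360 and 1283 FPKM in the same order. No marker of fibroblasts or of granulocytes and mast cells had a mean of 1 FPKM, and of 16 lymphocyte markers found only Ighm did, at up to 138.8 FPKM. Of 14 dendritic cell markers found, Cd74, at up to 187.3 FPKM, and Bst2 reached that mean.

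HU against control asked what the drug does to these cells. Targets of p53, the transcription factor activated by DNA damage, were much higher in HU, and mitotic genes were lower. Cdkn1a, the cell cycle inhibitor p21, was 6.54-fold higher (95% counting interval 6.25 to 6.84), from 63.0 to 411.7 FPKM. Mdm2, the ubiquitin ligase that restrains p53, was 6.59-fold higher (6.29 to 6.91). Plk1, a kinase required for mitosis, was 4.96-fold lower in HU (4.52 to 5.45), at 13.0 against 64.6 FPKM.

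Of 27 measured p53 targets, 22 were above counting error and 18 were at least 2-fold higher, with a median log2 ratio of 1.23 at percentile 100 of matched random lists. Phlda3, an inhibitor of AKT signalling, was 35.0-fold higher (24.2 to 52.4). Trp53inp1, a p53 target with a role in autophagy, was 54.9-fold higher (39.3 to 78.9), from 35 to 2569 reads. Both lie among the 10 highest genes of the contrast, with Epha2 (20.6-fold), Fam212b (38.4-fold), the thiamine transporter Slc19a2 (7.01-fold), Ddit4 (6.89-fold), Bbc3 (5.99-fold) and Ddias (5.94-fold). Cdkn1a lies on chromosome 17 at 29090976 to 29100727 and Mdm2 on chromosome 10 at 117688875 to 117710758 of mm10.

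Of 39 mitotic genes, 38 were below counting error and 11 were at least 2-fold lower (median log2 ratio -0.76, percentile 0). Cenpf was 4.02-fold lower (3.65 to 4.44), Aspm 3.15-fold lower (2.87 to 3.45) and Aurka 2.53-fold lower (2.37 to 2.71). The lowest gene by the naming rule was the helicase Pif1, 7.33-fold lower (6.37 to 8.46), followed by Plk1 and Prr11 (4.45-fold lower). The linker histone gene H1f0 was 3.29-fold lower (3.14 to 3.45). The 7 measured replication histone genes had a median of -0.61, with 3 below counting error, and rest on few reads in part (Hist1h2af, 51 against 12 reads). Their median was -0.24 with a pseudocount of 5 FPKM, and that of 54 members with mean FPKM above 0 was -0.20.

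Genes of DNA replication were higher in HU, with 27 of 37 above counting error and a median of 0.19 (percentile 100). Cdc6, a licensing factor, was 1.55-fold higher (1.45 to 1.66), whereas the kinase subunit gene Dbf4 was 1.78-fold lower (1.66 to 1.91). The G1/S and E2F list had a median of 0.23 (percentile 99.99), led by Ccne2 at 2.23-fold higher (2.05 to 2.42). Nucleotide synthesis genes had a median of 0.10 (percentile 99.8). Among the subunits of ribonucleotide reductase, Rrm2 was 1.25-fold higher (1.21 to 1.30), while the intervals of Rrm1 (0.986-fold, 0.955 to 1.02) and Rrm2b (1.04-fold, 0.896 to 1.20) included 1.

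Several death genes were higher in HU, and survival genes were slightly lower as a list. Of 31 pro-death genes, 12 were above and 7 below counting error (median 0.05, percentile 95.3), and 5 were at least 2-fold higher. The 28 members with mean FPKM of at least 5 had a median of 0.13 and stood apart (percentile 99.99). The 5 genes were Bbc3, which encodes PUMA, Tnfrsf10b (3.61-fold, 2.89 to 4.55), Fas (2.53-fold, 1.98 to 3.26), Dffb (2.37-fold) and Pmaip1, which encodes NOXA (2.09-fold, 1.95 to 2.24). Bax was 1.25-fold higher (1.19 to 1.31). Pro-survival genes had a median of -0.14 (percentile 0.33), with Pim1 1.86-fold lower (1.73 to 2.00) and Cflar 1.47-fold lower (1.38 to 1.57). Bcl2 had 127 and 178 reads, and its ratio of 1.05 (0.830 to 1.33) was within counting error.

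The core autophagy genes had a slightly lower median in HU, with 28 of 42 members within counting error. Of 42 measured, 11 were below and 3 above counting error, beside 20.1% and 18.7% of all genes with mean FPKM of at least 1. The median was -0.07 at percentile 2.48, a call that 4 of 7 alternative settings ended (percentile 2.87 with a pseudocount of 0.1 FPKM). Ulk1, the kinase that starts autophagosome formation, stood out at 3.15-fold higher (2.82 to 3.54). Becn1 (0.95-fold, 0.885 to 1.02) was within counting error, Map1lc3b was 1.12-fold lower (1.01 to 1.24) and Sqstm1 was 1.04-fold higher (1.01 to 1.07). Among 26 regulators of autophagy the median was -0.02 (percentile 44.0), but Trp53inp1, Ddit4, Sesn2 (3.98-fold, 3.73 to 4.25) and Foxo3 (2.59-fold, 2.41 to 2.78) were all at least 2-fold higher. Lysosomal genes had a median of -0.07 (percentile 0.03), with 20 of 53 below counting error.

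Interferon-stimulated genes were lower in HU (median -0.26, percentile 0), with 16 of 27 below counting error. The median was -0.13 with a pseudocount of 5 FPKM and -0.082 over 47 members with mean FPKM above 0, and the list stood apart under both. Rtp4 was 3.09-fold lower (2.19 to 4.44) and Irf9 1.95-fold lower (1.72 to 2.20), but the peptide transporter gene Tap1 was 2.93-fold higher (2.59 to 3.33). Of 29 inflammatory genes, 16 were below and 6 above counting error (median -0.11, percentile 0.02; -0.18 over the 25 with mean FPKM of at least 5). Tnf was 1.63-fold lower (1.59 to 1.68) and Ccl4 1.62-fold lower, whereas Ptgs2, which encodes the inducible cyclooxygenase, was 3.33-fold higher (3.09 to 3.60). Immediate early genes were higher as a list (median 0.19, percentile 100; 0.12 over the 21 with mean FPKM of at least 5), with Btg2 at 4.33-fold and Jun at 2.85-fold. The NRF2 antioxidant list (median 0.11, percentile 99.98) and the metal response list (median 0.22, percentile 99.9) were higher too, with Srxn1 at 1.73-fold and Slc30a1 at 2.12-fold. With all members of mean FPKM above 0, the metal response list had a median of 0.036 and did not stand apart (percentile 79.3). Cholesterol synthesis genes were lower (median -0.13, percentile 0.05), with 11 of 24 below and none above counting error.

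The integrated stress response list stood apart on the low side (median -0.07, percentile 1.06), although Ddit4 and Sesn2 belong to it. Chac1 was 2.26-fold lower (2.02 to 2.54) and Ddit3, which encodes CHOP, 1.78-fold lower (1.52 to 2.08). ER chaperone genes had a median of -0.06 (percentile 1.5) and macrophage identity genes one of -0.08 (percentile 0.84), in which Cebpa was 2.63-fold higher. Over 25 members with mean FPKM above 0, the macrophage identity median was -0.037 and did not stand apart (percentile 6.965). Mitochondrially encoded genes had a median of 0.09 (percentile 98.4), and their share of reads was 2.95% in control and 3.15% in HU. None of these 4 lists stood apart from unmatched random lists, where they lay at percentiles 4.7, 9.8, 4.72 and 94.9. The further lists that did not stand apart were heat shock, lipid handling, glycolysis and hypoxia, OXPHOS, ribosomal proteins, osteoclast, uptake and scavenging, DNA repair and housekeeping. After subtraction of length and GC trends the DNA repair list did (percentile 99.4).

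In all, 168 genes were at least 2-fold higher and 111 lower in HU among 11159, beside a median of 88.5 for counting noise alone. Among protein-coding genes these numbers were 92 and 41, beside a noise median of 2. In total 19 of 30 lists stood apart, where chance gives 1.5 if genes vary independently. Members of a list can vary together, and some lists share genes, as with Ddit4 and Sesn2. The 19 lists are thus not 19 separate responses. Of 1334 GO terms, 41 passed the bounds, where chance gives 13.3 under the same assumption. The lowest medians were those of spindle microtubule (-0.28), establishment of mitotic spindle orientation (-0.26) and nucleosome (-0.24), and the highest included BMP signaling pathway (0.14) and intrinsic apoptotic signaling by p53 (0.11).

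**Figure D1:**
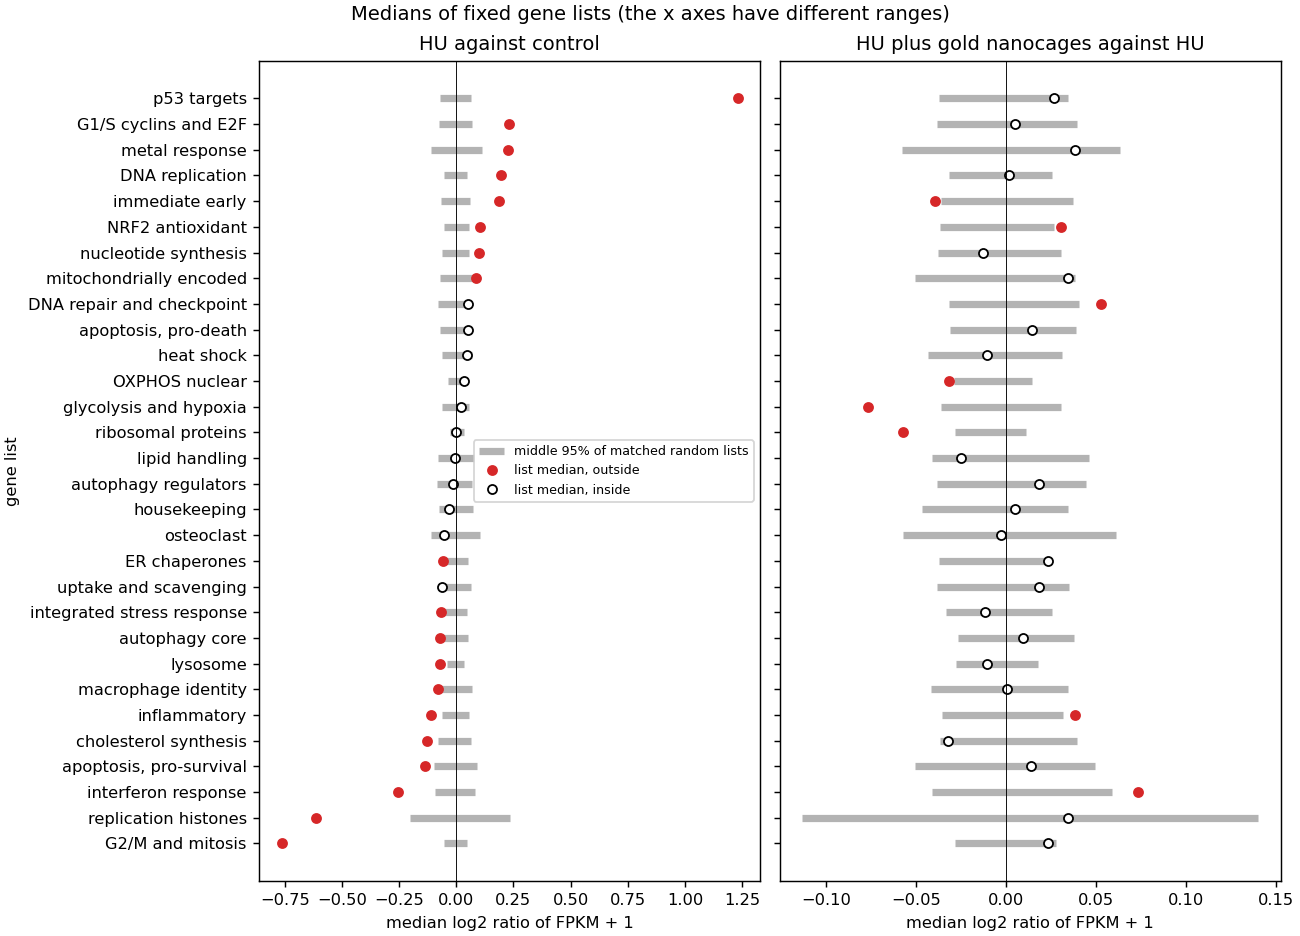
Medians of 30 fixed gene lists on the x axis (log2 ratio of FPKM plus 1), for HU against control on the left and HU plus gold nanocages against HU on the right, with different x ranges; grey bars hold the middle 95% of matched random lists, and filled points lie outside them. The p53 list lies at 1.23 and the mitosis list at -0.76 on the left, while every list on the right lies between -0.08 and 0.08.

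HU plus gold nanocages against HU addressed what the nanocages add when given at the same time as HU. Cdkn1a, Mdm2 and Plk1 were at nearly the same level in both libraries. Cdkn1a was at 401.0 FPKM with nanocages against 411.7 without (0.974-fold, 0.954 to 0.995), Mdm2 was at 173.8 against 171.8 FPKM and Plk1 at 13.2 against 13.0 FPKM. The p53 list had a median log2 ratio of 0.03 (percentile 93.8) and the mitosis list one of 0.02 (percentile 95.6). With all 32 members of mean FPKM above 0 the p53 list stood apart, at a median of 0.037 (percentile 98.7). A few genes of metal handling and oxidative stress were higher with nanocages, and genes of glycolysis and the ribosome were slightly lower as lists.

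Mt2, a metallothionein that binds zinc and copper, was 1.40-fold higher with nanocages (1.31 to 1.51), and Mt1 was 1.27-fold higher (1.21 to 1.33). The zinc exporter gene Slc30a1 was 1.40-fold higher (1.26 to 1.57). Of 9 metal response genes, 4 were above and none below counting error, but the list median of 0.04 did not stand apart (percentile 89.5). Hmox1, which encodes heme oxygenase 1, was 1.31-fold higher (1.26 to 1.36), Slc7a11 1.20-fold (1.12 to 1.28) and Gclc had a log2 ratio of 0.19. The NRF2 list, with 9 of 27 above and 2 below counting error, had a median of 0.03 (percentile 98.7), which did not stand apart from unmatched random lists (percentile 89.8). All 4 of Mt1, Mt2, Slc30a1 and Hmox1 were already higher in HU than in control.

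Glycolysis and hypoxia genes were lower with nanocages (median -0.08, percentile 0), with 15 of 27 below counting error. Hk2, a hexokinase gene, was 1.11-fold lower (1.05 to 1.16), and Pgk1 had a log2 ratio of -0.19. Of 57 ribosomal protein genes, 28 were below and 1 above counting error (median -0.06, percentile 0), with Rplp2 at a log2 ratio of -0.19. Nuclear genes of oxidative phosphorylation had a median of -0.03 (percentile 1.44). In HU plus gold nanocages against control these 3 lists lay within the bounds. Their medians were -0.025 for glycolysis and hypoxia (percentile 26.9), -0.038 for ribosomal proteins (3.69) and -0.021 for oxidative phosphorylation (25.0). The lower values thus stood apart only relative to the single HU library. Interferon-stimulated genes were higher as a list (median 0.07, percentile 99.3), with 5 of 27 above counting error, among them Rtp4 (1.59-fold, 1.09 to 2.35) and Ifi44 (1.32-fold, 1.11 to 1.58). This call was lost when all members with a mean FPKM above 0 were used (percentile 72.5).

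Immediate early genes (median -0.04, percentile 1.58), inflammatory genes (0.04, percentile 98.9) and DNA repair genes (0.05, percentile 99.4) also passed the bounds. After subtraction of gene length and GC trends these 3 lists did not, at percentiles 4.75, 83.8 and 92.9. Ier3 was 1.30-fold lower (1.20 to 1.42), and Il1b 1.56-fold lower (1.17 to 2.09) on 77 against 129 reads. In all 8 of 30 lists stood apart. The mitochondrially encoded list (median 0.03, percentile 96.8) did so only with a pseudocount of 5 FPKM or a mean FPKM of at least 5, at percentile 97.8 in both.

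Autophagy and death genes were close to equal in both libraries. The 42 core autophagy genes had a median of 0.01 (percentile 58.0), with 4 above and 4 below counting error. Map1lc3b (1.00-fold, 0.908 to 1.10), Becn1 (1.01-fold, 0.942 to 1.08) and Ulk1 (1.04-fold, 0.967 to 1.11) were within counting error, and Sqstm1, the selective autophagy receptor, was 1.06-fold higher (1.03 to 1.09). Autophagy regulators had a median of 0.02 (percentile 76.1) and lysosomal genes one of -0.01 (percentile 31.9). Pro-death genes had a median of 0.01 (percentile 72.6), with Fas 1.28-fold higher (1.09 to 1.5) and Bax 1.07-fold lower (1.03 to 1.12). Pro-survival genes had a median of 0.01 (percentile 72.1). Mcl1, a pro-survival BCL2 relative, was 1.15-fold higher (1.12 to 1.17), and Bcl2 was within counting error (1.17-fold, 0.947 to 1.44). Rrm1, Rrm2 and Rrm2b were within counting error.

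Among 11142 genes, 64 were at least 2-fold higher and 69 lower, and counting noise alone gave a median of 77 (59 to 103 over 100 draws). Only 6 of these 133 were protein-coding, 4 higher and 2 lower, where noise gave a median of 2 and a range of 0 to 6. The extremes of the naming rule were mostly small RNAs and pseudogenes with few reads, such as Rn7sk (28 against 69 reads), Mir763 (16 against 2) and the pseudogene Rps26-ps1 (218 against 42). The ribosomal RNA gene Rn18s-rs5 was 2.21-fold higher (2.12 to 2.30), at 405 against 184 CPM and 225 in control. Gm23935, annotated as a microRNA and chosen after its values were seen, had 406, 200 and 295 CPM in the same order, so both were highest in the library with nanocages. The phosphatase regulator gene Ppp1r14b was 2.0-fold higher (1.9 to 2.2), from 1625 to 3086 reads. It lies on chromosome 19 at 6974968 to 6977324 of mm10 and overlaps Plcb3 on the other strand, at 0.987-fold (0.904 to 1.08). Its pseudogene Gm7332 had 876 and 729 reads; Plcb3 and Gm7332 were looked up after the difference was seen. Rps27rt, a retrotransposed ribosomal protein gene that can share reads with its parent, was 1.69-fold lower (1.58 to 1.82). Of 1334 GO terms, 19 passed the bounds where chance gives 13.3 if genes vary independently. Symporter activity was lowest (-0.06) and peptide antigen binding highest (0.10). A further low term, GPI-anchor transamidase activity, is given in the deposited annotation to general hydrolases as well.

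**Figure D2:**
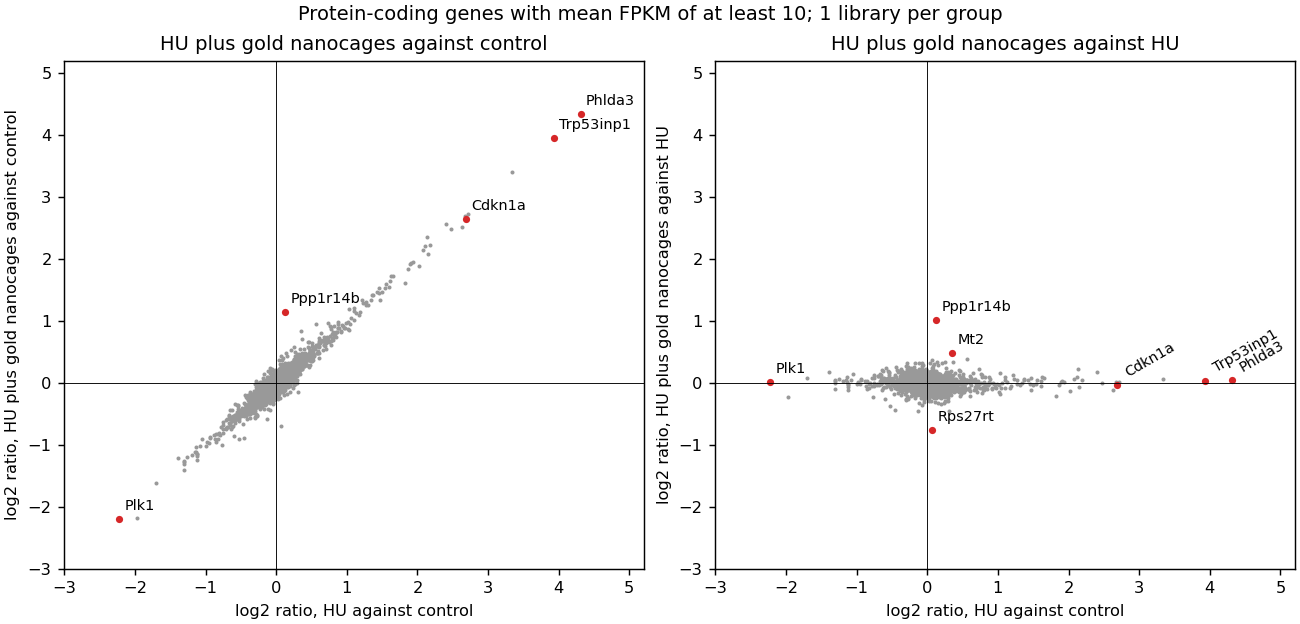
Log2 ratios (FPKM plus 1) of 5287 protein-coding genes with mean FPKM of at least 10, each point a gene, with HU against control on both x axes and HU plus gold nanocages against control (left) or against HU (right) on the y axes. Points on the left follow the diagonal, with Cdkn1a at 2.69 and 2.65, and Ppp1r14b stands at 1.02 on the right; the panels share the control and the HU library, respectively, which by itself ties the axes.

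HU plus gold nanocages against control had p53 targets high and mitotic genes low, as in HU alone. Phlda3 was 36.1-fold higher (25.0 to 54.1), Mdm2 6.67-fold higher (6.37 to 6.99) and Cdkn1a 6.37-fold higher (6.09 to 6.67). Pif1 was 6.28-fold lower (5.48 to 7.21) and Plk1 4.87-fold lower (4.43 to 5.37). The p53 list had a median of 1.43 and the mitosis list one of -0.80, with 18 of 30 lists standing apart. Pro-death genes had a median of 0.07 (percentile 98.2, and 95.2 after subtraction of length and GC trends) and DNA repair genes one of 0.12 (percentile 99.9). Nucleotide synthesis (percentile 97.495), ER chaperone (5.455) and mitochondrially encoded genes (97.2) lay within the bounds, and each passed them under at least 1 other setting. These 5 lists fell on different sides of the bounds in the contrasts of HU and of HU plus gold nanocages with control, but the differences between the contrasts were not tested. Slc30a1 was 2.98-fold higher (2.55 to 3.49), Hmox1 1.95-fold (1.85 to 2.05) and Mt2 1.79-fold (1.65 to 1.95).

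In this contrast 179 genes were at least 2-fold higher and 115 lower among 11167. Among 7435 protein-coding genes with FPKM of at least 5 in any library, 78 were higher in HU and 79 with nanocages, and 73 were in both sets. Lower genes numbered 33 and 29, with 28 in both, and none was apart in opposite directions. Independent lists would share 0.829 and 0.129 genes, but contrasts with the same control library are not independent. Counting noise around a common level put a median of 0 genes apart in either contrast, so it gives no reference for the overlap. Over 5287 genes the covariance of both contrasts was 0.0747, against 0.00187 for counting noise with a shared control. Part of the overlap may come from the shared control culture, which 1 library cannot separate.

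**Figure D3:**
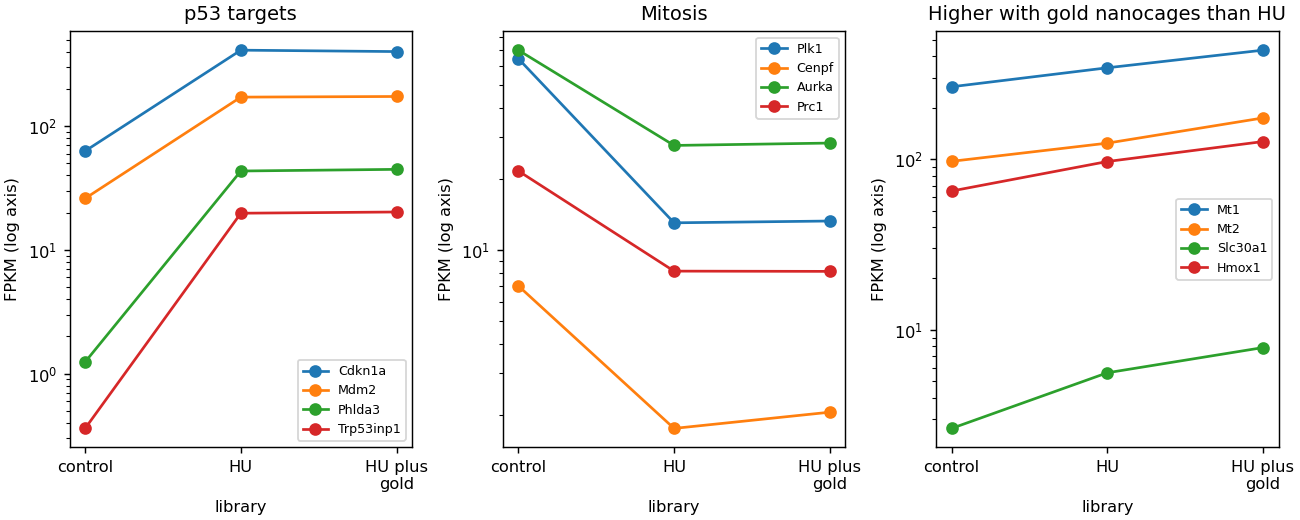
FPKM on a log axis of 4 p53 targets, 4 mitotic genes and 4 genes higher with gold nanocages, each point 1 library and each line joining the values of 1 gene. Cdkn1a lies at 63.0, 411.7 and 401.0 FPKM in control, HU and HU plus gold nanocages, and Mt2 at 97.1, 124.0 and 174.2.

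The question of rescue was put to the genes set apart by HU. HU and nanocages were given at the same time, so rescue of cells already damaged was not tested. Phlda3, Mdm2, Bbc3 and Plk1 lay at 44.8, 173.8, 65.8 and 13.2 FPKM with nanocages, beside 43.4, 171.8, 65.7 and 13.0 in HU. Among 111 protein-coding genes at least 2-fold apart with FPKM of at least 5, none lay 50% or more of the way back to control (exact 95% upper bound 3.27%), and the median return was 0.73% of the log2 distance. The gene farthest back was the linker histone gene Hist1h1c, at 43.4% of the distance (14.7, 5.75 and 8.73 FPKM in control, HU and HU plus gold nanocages). Among all 279 genes, 64 lay 50% or more of the way back, 22.9% (exact 95% interval 18.1 to 28.3), where counting noise alone gave a median of 14.7% (10.5 to 19.9). The draws added counting noise to counts that already held it, and they chose a median of 358.5 genes. Their share is thus not a matched reference, and an excess of return cannot be read from it. The mirror question took the 133 genes 2-fold apart between both HU libraries. Of these, 43.6% had a control value at least 50% of the way from HU to HU plus gold nanocages. No noise share was drawn for it, and counting noise alone put a median of 77 genes this far apart. The mirror share is thus no measure of return. The HU reads were also split at random, with 1 part to choose genes and set the distance to control, and 1 as the start of the return. The share was then 12.6%, of a median of 338 genes. Because the distance came from the part that chose the genes, the share with split reads is no independent measure of return.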

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

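The biotype, split-read and length and GC settings were chosen after the data were seen; the other settings were planned. No paired analysis was possible because each group holds 1 library, and for the same reason no library could be left out. The restriction to protein-coding genes by the table's own biotype was not run, as the table gives none. No result changed sign in a called value. Of 537 recomputed list medians 534 stayed within their interval; the mitosis median in HU against control was -0.61 with a pseudocount of 5 FPKM, the interferon median there was -0.082 with all members of mean FPKM above 0, and the ribosomal protein median with nanocages against HU was -0.038 after length and GC subtraction, where 5 lists stood apart. The other 20 counts of lists standing apart stayed within 1.5 times. Of 468 values of named genes, 60 left their counting interval, none with a change of sign beyond counting error.

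The numbers of genes 2-fold apart depend on the floor. For HU against control, nanocages against HU and nanocages against control in turn, they were 479, 243 and 489 with a pseudocount of 0.1 FPKM, 64, 6 and 64 with 5 FPKM, 132, 21 and 137 with a filter at 5 FPKM, and 672, 264 and 708 at 1.5-fold. Scaling each library to the same larger sum gave 711, 528 and 760, since values became larger against the same pseudocount and filter. Protein-coding genes alone gave 133, 6 and 131. Median-of-ratios scaling gave 275, 127 and 287, and moved the median of all genes by less than 0.01 on the log2 scale. Returning genes were 62.7% when any distance counted, 4.69% with a pseudocount of 5 FPKM, 6.06% with a filter at 5 FPKM, 0% for protein-coding genes with that filter, and 12.6% with split HU reads. With terms of 10 to 500 members, 74, 29 and 78 of 2049 GO terms passed. Depth limits low genes most, as counting noise alone put a median of 77 genes 2-fold apart between both HU libraries.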

Other observations

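A few transcripts linked to protection against hypertonic stress were lower with gold nanocages than with HU alone. Slc5a3, the myo-inositol carrier, was 1.30-fold lower (95% counting interval 1.23 to 1.37), the betaine carrier gene Slc6a12 1.15-fold (1.11 to 1.19), the amino acid carrier gene Slc38a2 1.08-fold (1.06 to 1.11) and Nfat5, the transcription factor that drives such genes, 1.08-fold (1.05 to 1.10). The organic anion carrier gene Slco4a1 was 1.36-fold lower (1.30 to 1.41). In HU against control, without nanocages, Slc38a2 (1.23-fold), Nfat5 (1.20-fold), Slc6a12 (1.12-fold), Slc5a3 (1.06-fold) and the chaperone gene Hspa4l (1.25-fold) were already lower, as was Slc6a6 (1.07-fold), while Akr1b3, Pnpla6 and Ranbp3l were within counting error. The carrier genes and Nfat5 were named after their values were seen. Cebpb was 1.26-fold higher (1.20 to 1.33), and the heat shock gene Hspa1b was 2.01-fold lower (1.45 to 2.83) on 54 against 117 reads.

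The tests of unseen NFAT5 targets and of length and GC were set before their results were seen; the tests of counting error, scaling, the NRF2 list and the number of libraries were chosen afterwards. For the osmolyte genes, the highest upper bound of the 4 folds was 0.949. These genes were taken up after their low values were seen, so the bound is no independent test of counting error. Median-of-ratios scaling shifted all genes by a median of only -0.0037 and so left library scaling untested. A candidate explanation is lower NFAT5 activity, with nanocages against HU. It was tested on targets not looked at before, of which 5 were measured: their median log2 ratio was -0.17, at percentile 0.08 of matched random lists, and 4 of 5 (Akr1b3, Slc6a6, Hspa4l and Pnpla6) were below counting error, while Ranbp3l was within it (0.730-fold, 0.512 to 1.03). Hspa4l, at a log2 ratio of -0.27 the lowest of the 5, also belongs to the heat shock list. Its value had already been computed when the targets were chosen, although it had not been looked at. Sgk1, at 25 reads in both libraries, was too low to be measured. Whether repeat cultures differ by as much cannot be told apart from an effect of nanocages with 1 library per group, and osmolality was not measured here.

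For Mt1, Mt2, Slc30a1 and Hmox1, the lowest lower bound of the 4 folds was 1.21. These genes were taken up after their high values were seen, so the bound is no independent test of counting error. Library scaling was left untested, since median-of-ratios scaling shifted all genes by a median of only -0.0037. The NRF2 list without Hmox1 stood at percentile 97.9 with a median of 0.03, which is consistent with a small shift of NRF2 targets, although the same list had been seen with Hmox1. A response to metal or to oxidants may underlie these genes, but the metal response list did not stand apart (median 0.04, percentile 89.5). A difference between cultures of 1 condition stays open, because there was 1 library per group and no library of nanocages without HU was analysed here.

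For the lists of ribosomal proteins, OXPHOS and glycolysis, low with nanocages against HU, a trend of gene length or GC between the libraries was tested as the whole cause. The GC bins with the lowest and highest GC had medians of 0.05 and -0.02. After subtraction of both trends the list medians stood at percentiles 0.01, 2.185 and 0, so the trends are argued against as the whole cause, narrowly for OXPHOS. The ribosomal protein median moved from -0.06 to -0.038, so part of that shift may follow length or GC. Rn18s-rs5 and Gm23935 were also about 2-fold higher in this library than in HU, so a difference in RNA or library preparation stays open. A difference between cultures was not testable with these libraries, and no biological explanation was tested.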
